A study of Mus musculus with 48 samples.

How the data were processed

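The series holds 48 single-colour Agilent arrays of mouse AECII and PASMC in 6 groups of 8. Each cell type was given as control and with an extract of e-cigarette vapour (ECVE, 15%, 24 h). The liquid it was made from held 0 or 18 mg/ml nicotine. Per the labels' protocols the cells were cultured with 10% (AECII) or 15% (PASMC) serum and came from C57Bl/6J mice. The labels number the arrays of each group from 1 to 8 but do not say which number is which mouse, so arrays were treated as independent, and effects within a mouse could not be tested. Groups were taken from the labels alone.

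The deposited matrix gives 1 log2 value per feature and array. The submitters' processing notes name limma, without a version or a step. The lowest value (1.52 to 1.53), lower quartile (2.25), median (2.97 to 2.98), upper quartile (5.78) and highest value (15.89) of the arrays coincide, so the deposited log2 values had been quantile normalised, and intensities on the original scale were not analysed here. The matrix has 62976 features, of which 31465 carry a gene name and 31511 do not, and 28 missing values. Names were brought to the symbols of the RefSeq gene table for mouse assembly GRCm38 by accession (29050 features) or kept or matched by synonym (2415), which changed 3282 names.

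Each of the 20738 genes was represented by its feature with the highest mean, chosen over all arrays without regard to group (6171 genes had several features). A gene was tested if its mean over the arrays of the fit exceeded 2.73, the 30th percentile of the means of all named features. This left 14477 genes in AECII, 14545 in PASMC and 14775 where both cell types were compared. The number of arrays, 8 per group, limits the precision.

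Models were fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3) by lmFit and eBayes on the deposited log2 values, with 1 coefficient per group and all 24 arrays of a cell type in 1 fit, or all 48 where cell types were compared. Comparisons were each extract against control, both extracts against each other, the cell types at control, and the difference of the responses between cell types. All tests were two-sided, p values were adjusted by Benjamini and Hochberg within each comparison, and genes were called at an adjusted p under 0.05. Genes named in the report are all those called up to 10 per direction, the 5 with the smallest p where none was called, up to 4 members of a called list or all that passed when adjusted over the list alone, and a set of readouts (Cyp1a1, Cyp1b1, Nqo1, Hmox1, nicotinic receptor genes, Sftpc, Acta2). Smtn, the cell-type markers such as Marco, Chil3 and Lyz2, and a few genes carried over from another comparison were added after the values were seen. Values of genes with a mean near the array median are called near background.

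A total of 34 gene lists with 713 genes were written down from general knowledge. Of these genes 689 have a probe on the array, and 24 have none and were not analysed here. Lists were tested with camera (preset correlation 0.01, p adjusted over the 34 lists), and again with the correlation between genes estimated from the arrays and with fry, which asks whether the genes of a list move one way without comparing them with other genes. Counts of changed genes are given over all genes and adjusted over the list alone. For the called lists of the treatment comparisons the mean over the list was computed in each array and compared by an exact permutation of the 16 arrays, adjusted over the lists tested this way. The lysosome list of PASMC and the NRF2 list of AECII were compared in the same way between both extracts.

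The groups, comparisons, gene lists, filter, limma tests and most alternatives were chosen before the data were examined, and the exact permutations of list means after results were seen. Alternatives were the replicate number or runs of 8 accessions as a block, no filter or the 50th percentile, renewed quantile normalisation, median centring, all 48 arrays or only the 16 compared, treat with a minimum fold of 1.2, eBayes with trend and robust fitting, array weights, the mean of all probes of a gene, and leaving out each array in turn. Alternatives added later were 1 or 3 components of the residuals as covariates, and PASMC arrays with Sftpc at or below 6. Each count was set against 100 random splits of the same arrays (seed 11), and the lysosome and NRF2 lists against 10000 random lists of genes of the same brightness.

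The procedure was tested on simulated data with the variances of these arrays, 14477 genes in AECII and 14545 in PASMC, and 100 changed genes of each size. At a log2 change of 0.5 the comparison of the nicotine-containing extract with control recovered 30 of 100 genes in AECII and 23 of 100 in PASMC. At a change of 1 it recovered 85 and 72. The runs, each with both sizes, made 5 and 9 false calls. Noise was drawn independently for each gene and array, whereas in PASMC the first residual component held 32.9% of the residual variance. The threshold is also stricter when fewer genes change, so these rates are not the power of the real comparisons. Even in this simulation changes well under 1 were often missed with 8 arrays per group.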

Results

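Mouse alveolar epithelial type II cells (AECII) and pulmonary arterial smooth muscle cells (PASMC) were profiled on 48 single-colour arrays. The extract, given for 24 h, was one of e-cigarette vapour prepared from e-liquids (ECVE, 15%). Each cell type was given in 3 conditions of 8 arrays: control, extract made from a liquid with 0 mg/ml nicotine and extract made from a liquid with 18 mg/ml nicotine. The labels do not say what the control cells received. After probes were joined to genes, 20738 genes were available, and 14477 of them in AECII and 14545 in PASMC were bright enough to be tested. Arrays of the same cell type and condition correlated at 0.973 to 0.986 in AECII and at 0.937 to 0.986 in PASMC. All changes below are log2 differences with their standard error, and genes were called at an adjusted p under 0.05 (two-sided, limma). A group of genes was called at an adjusted p under 0.05 over the 34 lists.

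The controls show how the 2 cultures differ before any extract. Control AECII and control PASMC differed in 8744 of 14775 genes, 4124 higher in AECII and 4620 lower (n = 8 arrays each). The secretoglobin Scgb1a1, the main secreted protein of airway club cells, was 11.98 higher in AECII (standard error 0.72, adjusted p = 4.85e-19; 15.73 ± 0.047 against 3.76 ± 0.94, mean ± SD). As the scale of the arrays ends at 15.89, this difference is a lower bound. Next came the tetraspanin Tspan1 (9.75), the secreted protease inhibitor Wfdc2 (9.74) and the glutathione transferase genes Gsta1 (9.18) and Gm10639 (9.10). The keratin Krt7 (9.00), Mal2 (8.95), S100a14 (8.86), the tight-junction gene Cgn (8.79) and surfactant protein D, Sftpd (8.74), followed. Among the lowest in AECII relative to PASMC were the serine proteases Gzme (-9.02, standard error 0.38; 2.72 against 11.75) and Mcpt8 (-8.47; 2.48 against 10.95), then Ndufa4l2 (-7.77) and the cell-cycle inhibitor Cdkn2a (-7.65; 3.02 against 10.67). The nerve growth factor receptor Ngfr (-7.37), the mesenchymal surface marker Thy1 (-6.79), the matrix gene Thbs2 (-6.60), the glutamate carrier Slc1a6 (-6.44), the fibroblast protease Fap (-6.40) and Serpinf1 (-6.36) were also among them. Means near or below the array median of about 2.97, such as those of Gzme and Mcpt8 in AECII or Tspan1 in PASMC (2.88), are background, so differences against them are lower bounds and the order of these genes is not firm.

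The lung epithelial markers set AECII apart as a group. Of 20 alveolar type II markers 18 were higher in AECII and 1 lower (median 3.00, adjusted p = 1.23e-07), among them Sftpc (8.56, standard error 1.33), Sftpa1 (6.07), the transcription factor Nkx2-1 (4.93) and the surfactant-processing protease Ctsh (4.48). All 14 general epithelial markers were higher (median 5.56, adjusted p = 1.91e-12), led by Rab25 (6.60), Epcam (5.88), Esrp1 (5.24) and Grhl2 (4.60). Markers of other lung epithelia were also higher. This held for alveolar type I markers in 12 of 18 genes (Aqp5 7.70, Clic5 7.28; adjusted p = 5.16e-05, and 0.157 with an estimated correlation). Transitional markers were higher in 12 of 16 (Cldn4 7.12, Krt19 6.74; adjusted p = 1.8e-05, and 0.166 with an estimated correlation) and airway markers in 9 of 11 (Scgb3a1 7.07, Foxj1 3.07; adjusted p = 0.000288, and 0.0992 with an estimated correlation). All 7 mesothelial markers were higher in AECII, among them Lrrn4 (8.00), Upk1b (6.66), Upk3b (5.49) and Muc16 (4.45; list adjusted p = 6.75e-08).

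PASMC carried the mesenchymal programs. Contractile genes were lower in AECII in 19 of 22 cases and higher in none (median -2.08, adjusted p = 5.57e-07, and 0.0545 with an estimated correlation), with Actg2 (-5.75), Cnn1 (-4.56), Acta2 (-3.27, standard error 0.28; 11.71 ± 0.67 against 14.98 ± 0.34) and Myl9 (-2.63). Matrix genes were lower in 24 of 28 cases (Col8a1 -5.19, Col5a1 -3.56, Bgn -3.29; adjusted p = 4.9e-08) and metalloproteinases and their inhibitors in 14 of 18 (Adamts4 -5.13, Mmp2 -4.57; adjusted p = 5.77e-05). Fibroblast markers were lower in 9 of 16 genes and higher in 3 (Mfap5 -5.14, Dcn -3.48; adjusted p = 0.0115, and 0.374 with an estimated correlation). Hypoxia and glycolysis genes were lower in 22 of 26 (Slc16a3 -3.79, Slc2a1 -1.53; adjusted p = 5.57e-07), p53 targets in 17 of 21 (Zmat3 -1.87, Mdm2 -1.82; adjusted p = 4.5e-05) and autophagy and lysosome genes in 20 of 27 (Wipi1 -1.67, Hexa -1.60, Ctsl -1.56; adjusted p = 8.63e-05).

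Another 5 lists were higher in AECII, 4 of them not with an estimated correlation. Cholesterol synthesis genes were higher in 18 of 21 cases (Idi1 2.91, Hmgcs1 2.09; adjusted p = 1.23e-07, and 0.0545 with an estimated correlation), and cell-cycle genes in 18 of 36 (Mcm6 0.99, Cdt1 0.98; adjusted p = 0.000451, and 0.482 with an estimated correlation). NRF2 antioxidant genes were higher in 17 of 29 and lower in 7 (Gsta2 8.25, Gsta3 4.80, against Hmox1 -1.95 and Nqo1 -0.76; adjusted p = 0.000128, and 0.166 with an estimated correlation). Aryl hydrocarbon receptor targets were higher in 5 of 7 (Cyp2s1 5.50, Cyp1a1 4.67, Aldh3a1 3.71; adjusted p = 0.014), heat shock genes in 11 of 17 (Hspa4l 1.67, Hsp90ab1 0.50; adjusted p = 0.00449, and 0.2 with an estimated correlation). Of the nicotinic receptor subunits tested, Chrnb1 (3.06) and Chrnb4 (0.78) were higher in AECII and Chrna1 (-3.73) and Chrna7 (-0.76) lower. Chrnb4 and Chrna7 in both cell types, Chrna1 in AECII and Chrnb1 in PASMC lie near background, so the sizes of these differences are uncertain.

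The other 16 lists were not called by camera, although single genes in them differed and fry, which does not compare a list with other genes, called 26 of the 34 lists. Higher and lower genes in AECII numbered 9 and 7 of 21 for aldehyde metabolism (list adjusted p = 0.0765), 8 and 10 of 29 for ATF4 targets (0.646), 10 and 2 of 22 for endoplasmic reticulum chaperones (0.108), 1 and 2 of 4 for metallothioneins (0.433) and 10 and 9 of 25 for NF-kB and cytokine genes (0.901). They were 6 and 12 of 27 for interferon-stimulated genes (0.948), 12 and 6 of 23 for fatty acid synthesis (0.107), 4 and 10 of 23 for fatty acid oxidation (0.433), 5 and 9 of 30 for the mitochondrial respiratory chain (0.948) and 4 and 6 of 15 for iron handling (0.948). Immediate early genes gave 6 and 12 of 24 (0.289), TGF-beta targets 4 and 8 of 19 (0.162), nicotinic receptors 2 and 2 of 6 (0.909), macrophage markers 5 and 1 of 20 (0.433), lymphocyte markers 1 and 0 of 8 (0.799) and endothelial markers 2 and 2 of 14 (0.948). Median and mean differed in sign, or from the direction of the test (up), for NF-kB genes (0.39 and -0.11), interferon-stimulated genes (-0.58 and -0.077), nicotinic receptors (-0.073 and -0.13) and lymphocyte markers (-0.019 and 0.25). Counts of higher and lower genes adjusted over the list alone were the same as over all genes except for NRF2 genes (18 and 7), heat shock genes (12 and 2), metallothioneins (1 and 3), interferon-stimulated genes (6 and 13), fatty acid oxidation (5 and 10) and immediate early genes (6 and 13).

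Surfactant protein C, the classical product of alveolar type II cells, varied little in AECII and widely in PASMC (14.33 ± 0.30 against 5.77 ± 3.69 in controls). Control PASMC arrays ran from 1.72 to 11.28, all below the lowest AECII control (13.80). It exceeded 6 in 3 control, 4 nicotine-free and 4 nicotine-containing PASMC arrays of 8 each, so every condition had cultures with this message.

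**Figure D1:**
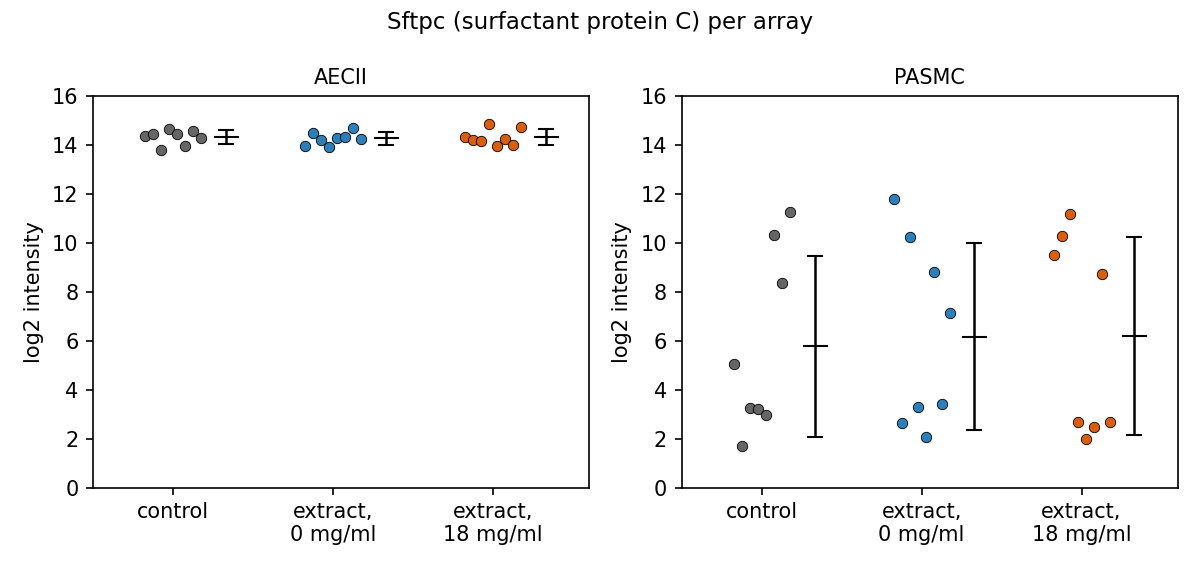
Sftpc in each array by condition (log2 value), AECII left and PASMC right. Points are arrays and bars are mean ± SD; AECII controls lie at 14.33 ± 0.30 and PASMC controls at 5.77 ± 3.69.

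The nicotine-free liquid shows what the extract does to alveolar cells without nicotine. In AECII given this extract, no gene passed adjustment (0 of 14477 in limma). At an unadjusted p under 0.05 there were 480, fewer than the 724 expected by chance for independent arrays. In the treatment comparisons within a cell type 1.94% to 4.05% of genes lay under this p. The gene tests treat arrays as independent and are insensitive if conditions share mice, so few calls do not show that effects are absent. Genes of the NRF2 antioxidant response, which detoxify electrophiles and rebuild glutathione, were shifted up as a group (27 of 29 positive, mean 0.15; n = 8 arrays each, adjusted p = 4.37e-06, and 0.857 with an estimated correlation). The best supported were the glutathione transferase Gsta1 (0.40, standard error 0.13), the carbonyl reductase Cbr3 (0.28, standard error 0.12), Gsta2 (0.44, standard error 0.24) and the glutathione reductase Gsr (0.16, standard error 0.070). None of the 29 passed when adjusted over the list alone, and 6 of 8 treated arrays lay above the control mean of the list. Exchanging whole arrays between the groups gave an exact p of 0.15, a test that treats arrays as independent and is insensitive if conditions share mice. Without control array 6, which was low in these genes, the list mean was 0.090.

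Single genes with the smallest p values in this comparison were Dcaf5 (-0.54, standard error 0.12) and, near background, Olfr1, Zhx2, Lbx2 and Krtap1-4, all with an adjusted p of 0.899 or more. Genes expected to respond to smoke constituents or nicotine had values of 0.032 for Cyp1a1 (standard error 0.46), 0.14 for Cyp1b1 (0.14), 0.34 for Nqo1 (0.26), -0.23 for Hmox1 (0.44) and 0.58 for the nicotinic receptor Chrna7 (0.22, adjusted p = 0.999), which lies near background. Without 1 low array Hmox1 turned to 0.27 (nicotine-free array 2), and Nqo1 fell to 0.15 (control array 6). Sftpc stood at -0.050 (standard error 0.14). Aryl hydrocarbon receptor targets (adjusted p = 0.207), aldehyde metabolism (0.139) and ATF4 targets (0.246) were not called.

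With 18 mg/ml nicotine in the liquid, again no gene of AECII passed alone (0 of 14477 in limma, 341 at an unadjusted p under 0.05). The NRF2 list was shifted up in all 29 of its genes (mean 0.23; 11.51 ± 0.20 against 11.28 ± 0.19, n = 8 arrays each; adjusted p = 5.65e-14, and 0.174 with an estimated correlation). Gsta1 (0.50, standard error 0.13) and Cbr3 (0.44, standard error 0.12) were 2 genes higher when adjusted over the list alone (adjusted p = 0.0189 each), and Gsta3 (0.40, standard error 0.15) and the epoxide hydrolase Ephx1 (0.31, standard error 0.11) came next. Of the 8 treated arrays 7 lay above the control mean, with an exact p of 0.0314 for the list mean (0.0691 adjusted over the lists tested this way).

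Aldehyde-clearing genes and targets of ATF4, the transcription factor of the integrated stress response, were shifted in the same direction by smaller amounts. The aldehyde list was positive in 20 of 21 genes (mean 0.13, adjusted p = 0.00189, and 0.104 with an estimated correlation), with Aldh1a7 (0.23, standard error 0.10), Aldh1a1 (0.17, standard error 0.081) and Aldh3a1 (0.31, standard error 0.17). ATF4 targets were positive in 26 of 30 genes (mean 0.096, adjusted p = 0.00431, and 0.256 with an estimated correlation), with Stc2 (0.52, standard error 0.26), Ddit3 (0.32, standard error 0.19) and the amino-acid carrier subunit Slc7a5 (0.19, standard error 0.11). Without control array 6 the ATF4 mean was 0.080 and the list was not called. No gene of either list passed when adjusted over the list alone. Exact p values for the list means were 0.0591 and 0.0306 (0.108 and 0.0691 adjusted), and 6 of 8 and 8 of 8 treated arrays lay above the control mean.

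**Figure D2:**
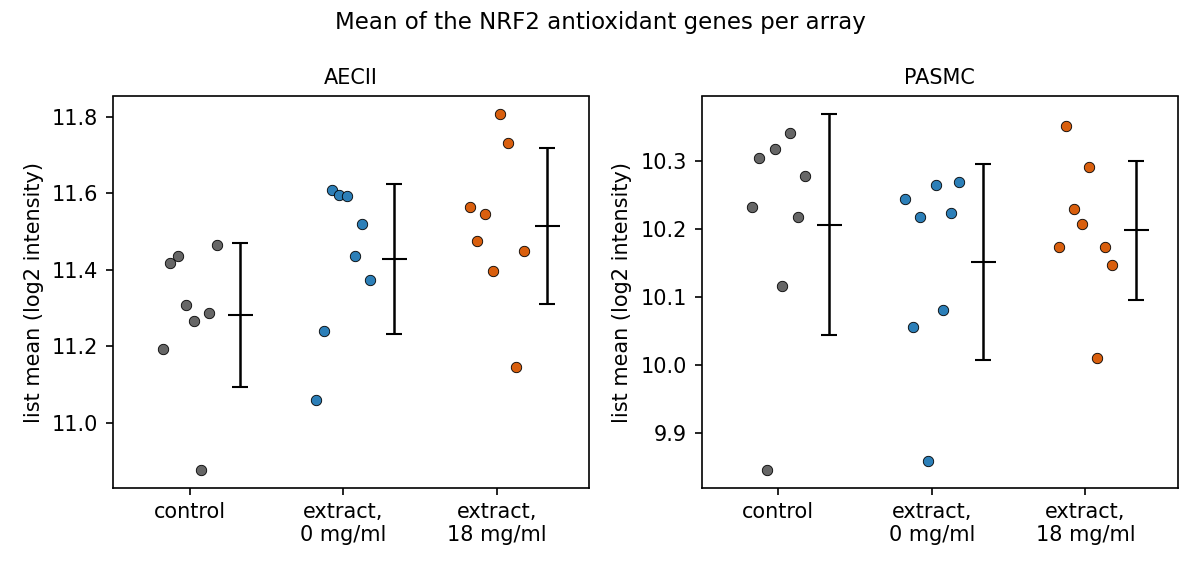
Mean log2 value of the 29 NRF2 antioxidant genes in each array by condition, AECII left and PASMC right, with y axes that differ and do not start at 0. Points are arrays and bars are mean ± SD; in AECII the list averaged 11.28 in controls, 11.43 with the nicotine-free and 11.51 with the nicotine-containing extract.

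B4galt7 (-0.57, standard error 0.13) and, near background, Serpinc1, Zfp786 and Abhd1 had the smallest p values beside Gsta1, each with an adjusted p of 1. Hmox1 stood at 0.51 (standard error 0.44), Nqo1 at 0.36 (0.26, but 0.17 without control array 6 and 0.54 without treated array 7), Cyp1a1 at -0.13 (0.46), Cyp1b1 at 0.14 (0.14) and Sftpc at -0.0049 (0.14). Among nicotinic receptors Chrna7 had a value of 0.62 (standard error 0.22) and Chrna1 0.51 (0.31), both near background and neither below an adjusted p of 1. Aryl hydrocarbon receptor targets (adjusted p = 0.0626), interferon-stimulated genes (0.0643), cholesterol synthesis (0.0741), NF-kB and cytokine genes (0.488), heat shock genes (0.488) and alveolar type II markers (0.994) were not called.

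The direct comparison of both extracts in AECII gave no gene (0 in limma, 447 at an unadjusted p under 0.05) and no list (smallest adjusted p 0.427). NRF2 genes were positive in 21 of 29 cases (median 0.075, adjusted p = 0.427). Kif3a (0.46, standard error 0.11), Nab1 (0.36), Gabbr1 (-0.64) and, near background, Fastkd2 and Krtap1-4 had the smallest p values, all with an adjusted p of 1. Hmox1 stood at 0.74 (standard error 0.44) but at 0.23 without nicotine-free array 2, and Chrna7, near background, at 0.048. The NRF2 list mean differed by 0.086 (exact p = 0.404, 6 of 8 arrays above), so an added effect of nicotine was not detectable with these arrays.

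In PASMC given the nicotine-free extract, genes of autophagy and the lysosome were lower as a group (21 of 27 negative, mean -0.10; 10.84 ± 0.030 against 10.95 ± 0.041, n = 8 arrays each; adjusted p = 1.81e-06, and 0.000157 with an estimated correlation). The smallest p values in the list came from subunits of the proton pump that acidifies the lysosome, Atp6v1h (-0.41, standard error 0.13) and Atp6v0d1 (-0.27, standard error 0.086). Cathepsin A, Ctsa (-0.25, standard error 0.085), and the lysosomal calcium channel Mcoln1 (-0.22, standard error 0.080) came next. All 8 treated arrays lay below the control mean, with an exact p of 0.000311 (0.00171 adjusted over the lists tested this way). No single gene of the list passed when adjusted over the list alone, and no gene passed over the transcriptome (0 of 14545 in limma, 402 at an unadjusted p under 0.05).

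Among single genes, the nucleotide-sugar enzyme homologue Uap1l1 (-0.75, standard error 0.14, adjusted p = 0.184) had the smallest p value and was below the control mean in 8 of 8 arrays. Fnip2 (-0.59, standard error 0.14), a partner of the folliculin complex at the lysosome surface, the creatine carrier Slc6a8 (-0.32, standard error 0.076), the lysosomal collagenase cathepsin K, Ctsk (-0.53, standard error 0.13), and Gnptg (-0.40, standard error 0.096), a subunit of the enzyme that tags hydrolases for the lysosome, followed with an adjusted p of 1.00. Ctsk and Gnptg are not members of the list.

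A further 3 lists were called in this comparison, all lost with an estimated correlation. Cell-cycle genes were shifted up in 34 of 36 cases (mean 0.14, adjusted p = 0.00011, and 0.941 with an estimated correlation), among them Kif20a (0.35), Prc1 (0.31), Cenpe (0.28, standard error 0.14) and Ccne1 (0.17). Hypoxia and glycolysis genes were shifted down in 23 of 26 (mean -0.13, adjusted p = 0.000336, and 0.538 with an estimated correlation), among them Slc16a3 (-0.30), Pfkp (-0.27), Pgam1 (-0.15) and Pgk1 (-0.11). Their exact p values were 0.271 and 0.261, and leaving out 1 array ended their calls (cell cycle 0.081 without nicotine-free array 4 and 0.090 without control 8, hypoxia -0.081 without control 3). Both checks treat arrays as independent. Control 3 and nicotine-free 4 belong to 1 trio of mutually similar arrays described below, so leaving out 1 of them may unbalance the conditions. Endoplasmic reticulum chaperones were shifted up in 17 of 22 (mean 0.078, adjusted p = 0.0321, and 0.248 with an estimated correlation), with Hyou1 (0.38), Pdia4 (0.34) and Pdia6 (0.11) and an exact p of 0.0199 (0.0691 adjusted). This call ended when any 1 of 8 of the 16 arrays was left out (means 0.059 to 0.084). No gene of these lists passed when adjusted over the list alone. Cyp1a1 stood at -0.13 (standard error 0.80), Nqo1 at 0.19 (0.18), Hmox1 at -0.30 (0.28, but -0.10 without nicotine-free array 4 and -0.47 without control array 3) and Acta2 at -0.0040 (0.20).

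With 18 mg/ml nicotine in the liquid, 4 of 14545 genes fell in PASMC and none rose (589 at an unadjusted p under 0.05). Uap1l1 fell most (-0.93, standard error 0.14, adjusted p = 0.00775; 9.87 ± 0.16 against 10.80 ± 0.34, n = 8 arrays each). Ctsk fell from 11.69 ± 0.33 to 10.98 ± 0.17 (-0.70, standard error 0.13, adjusted p = 0.0427). Kazn, a gene of cell-junction assembly, fell from 6.78 ± 0.28 to 6.04 ± 0.24 (-0.74, standard error 0.13), and the creatine carrier Slc6a8 from 12.22 ± 0.13 to 11.79 ± 0.14 (-0.43, standard error 0.076), both with an adjusted p of 0.0427 too. Every treated array was below the lowest control for Uap1l1, Ctsk and Kazn, and 7 of 8 were for Slc6a8. Kazn rests on its brightest probe, and the mean of all its probes was -0.22 and not called. Leaving out 1 array left Uap1l1 alone called for 14 of the 16 arrays. None of the 4 was called in a fit of only these 16 arrays, with treat, or without the arrays of high Sftpc. The same held with runs of 8 accessions or the replicate numbers as a block. Over all 31 alternatives Uap1l1 ranged from -1.02 to -0.88, Ctsk from -0.80 to -0.64 and Slc6a8 from -0.46 to -0.39.

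**Figure D3:**
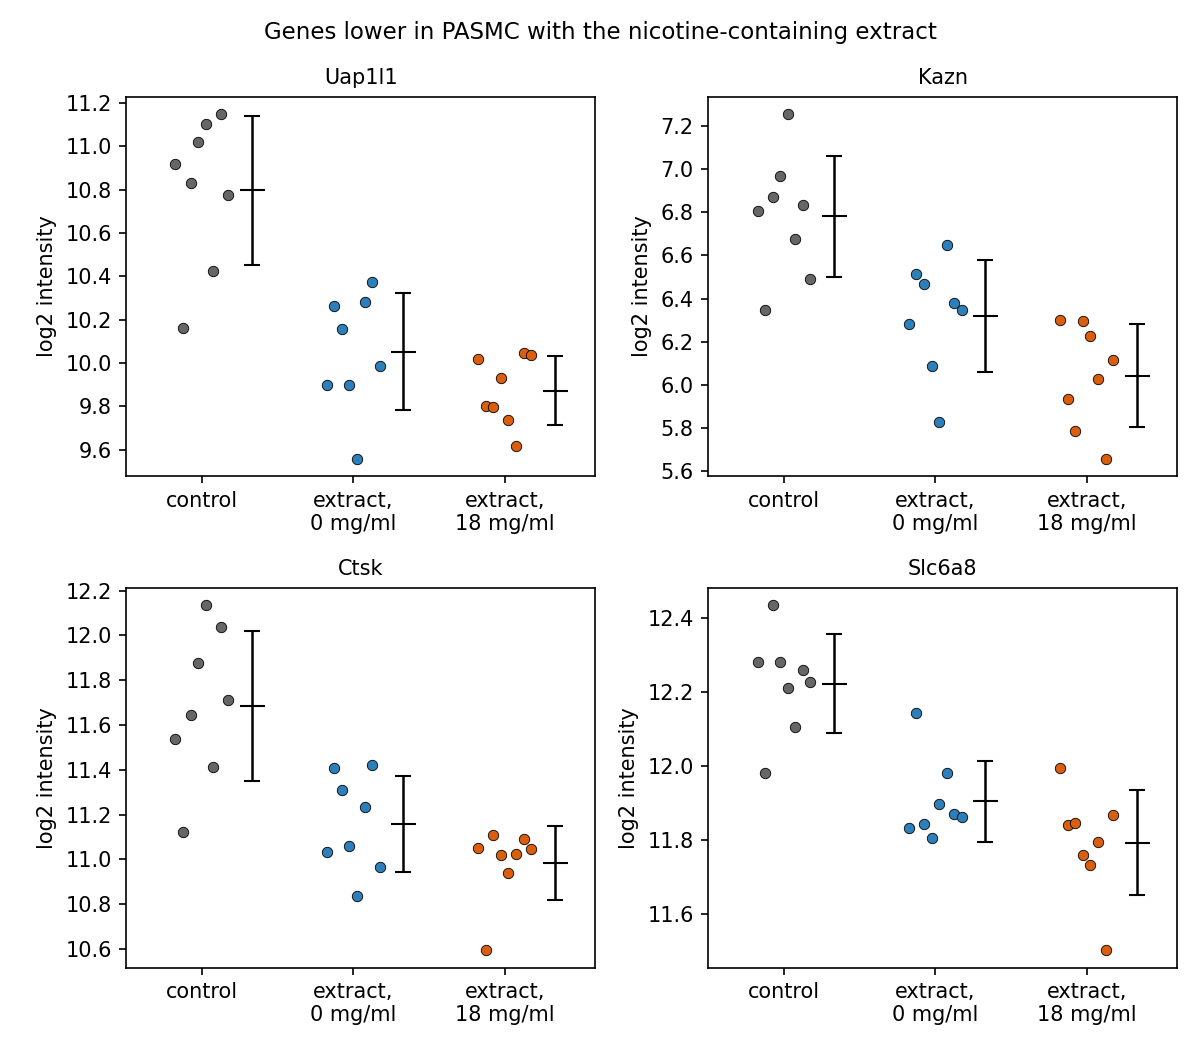
Log2 values of Uap1l1, Kazn, Ctsk and Slc6a8 in PASMC arrays by condition. Points are arrays and bars are mean ± SD; Uap1l1 averaged 10.80 in controls and 9.87 with the nicotine-containing extract.

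Autophagy and lysosome genes were lower as a group here too (22 of 27 negative, mean -0.15; 10.80 ± 0.025 against 10.95 ± 0.041; adjusted p = 1.63e-09, and 9.82e-06 with an estimated correlation). When adjusted over the list alone 7 genes were lower and none higher. They were Ctsa (-0.33, standard error 0.085), Atp6v1h (-0.47, standard error 0.13), the cysteine protease Ctsl (-0.24, standard error 0.077) and Mcoln1 (-0.25, standard error 0.080). The autophagy enzyme Atg7 (-0.34, standard error 0.12), the autophagosome protein Gabarap (-0.19, standard error 0.064) and Atp6v0d1 (-0.23, standard error 0.086) were the others. No treated array reached the lowest control (highest 10.85 against 10.90), so the exact p was the smallest that 12870 possible splits allow (0.000155, 0.0017 adjusted). The list was called in every alternative run for it, including the one without the arrays of high Sftpc (mean -0.14). Arrays of low Sftpc could still hold other epithelial transcripts. Control 2, nicotine-free 5 and nicotine-containing 5 had Krt7 at 8.89, 8.53 and 8.18.

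**Figure D4:**
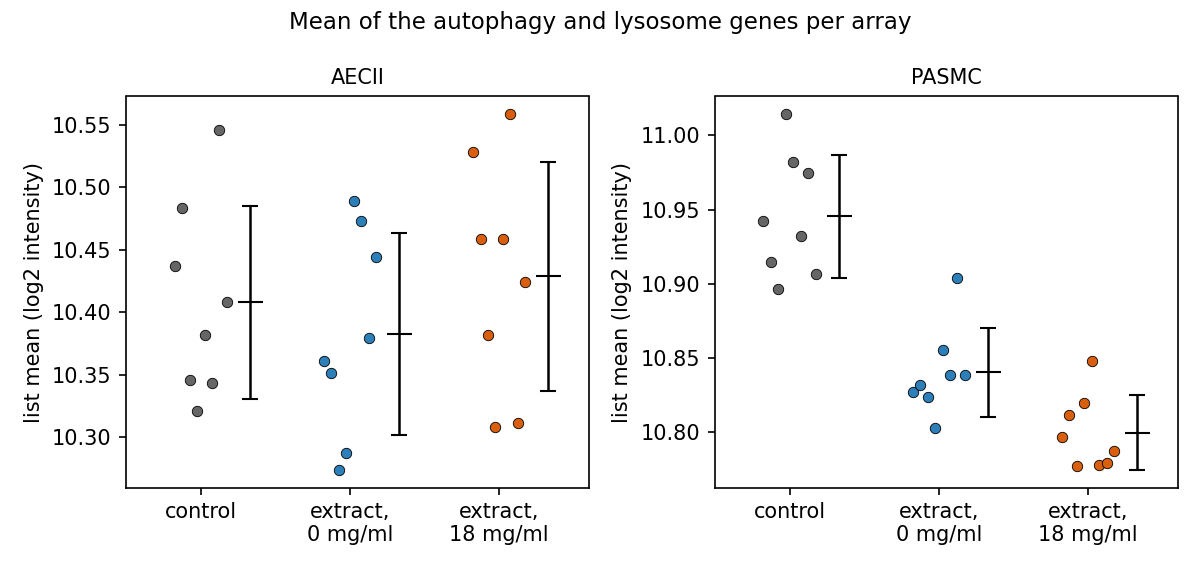
Mean log2 value of the 27 autophagy and lysosome genes in each array by condition, AECII left and PASMC right, with y axes that differ and do not start at 0. Points are arrays and bars are mean ± SD; in PASMC the list averaged 10.95 in controls, 10.84 with the nicotine-free and 10.80 with the nicotine-containing extract.

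Cell-cycle genes were shifted up in 32 of 36 cases (mean 0.15, adjusted p = 4.12e-05, and 0.967 with an estimated correlation; exact p = 0.324), with Kif20a (0.39), Cenpe (0.33), Ccne1 (0.27, standard error 0.11) and Birc5 (0.24). Without treated array 6 the mean was 0.065 and the list was not called. Hypoxia and glycolysis genes were shifted down in 22 of 26 (mean -0.14, adjusted p = 0.000173, and 0.475 with an estimated correlation; exact p = 0.194), with Egln3 (-0.33), Hk2 (-0.22), Pgam1 (-0.17) and Pgk1 (-0.15, standard error 0.061). No gene of these lists passed when adjusted over the list alone. The lectin gene Lgals3 (galectin-3), listed here with transitional epithelial markers, was lower when adjusted over the list alone (-0.61, standard error 0.15, adjusted p = 0.0073). That list was not called (median 0.085 and mean 0.041, test direction down).

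The contractile genes that define smooth muscle were not called (18 of 22 positive, adjusted p = 0.195), with Smtn at 0.35 (standard error 0.12) and Acta2 at -0.021 (standard error 0.20). Iron-handling genes (13 of 15 negative, adjusted p = 0.195), matrix genes (0.779), NF-kB and cytokine genes (median 0.026, mean -0.027, 0.94), NRF2 genes (15 of 29 positive, median 0.0090, mean -0.0090, 0.94) and macrophage markers (0.779) were not called either. Cyp1a1 stood at 0.20 (standard error 0.80), Nqo1 at 0.23 (0.18), Hmox1 at -0.29 (0.28), Chrna1 at 0.20 (0.67), and Chrna7, near background, at -0.31 (0.28). Without control array 3 Hmox1 was -0.47 and Chrna1 turned to -0.25.

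Between both extracts PASMC showed no gene (0 in limma, 282 at an unadjusted p under 0.05) and no list (smallest adjusted p 0.444). Autophagy and lysosome genes were negative in 20 of 27 cases with a median of -0.045 (adjusted p = 0.444, and 0.711 with an estimated correlation). Tctn3 (-0.91, standard error 0.22) and, near background, Gm10220, Wdr31, Wdr38 and Mansc1 had the smallest p values, each with an adjusted p of 1. The list mean was nevertheless lower with nicotine in 7 of 8 arrays (10.80 ± 0.025 against 10.84 ± 0.030, -0.041; exact p = 0.0087, 0.0174 adjusted over both lists tested this way), in a test chosen after the values were seen. Whether nicotine adds to the lower lysosomal genes therefore stays open. Acta2 stood at -0.017.

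The responses of both cell types to the nicotine-containing extract differed most clearly in the lysosome. AECII minus PASMC, the list mean was 0.17 (adjusted p = 1.06e-08, and 0.0044 with an estimated correlation), because it was lower in PASMC and not called in AECII (16 of 27 positive, adjusted p = 0.731; 10.43 ± 0.092 against 10.41 ± 0.077). Atp6v1h (0.53), Hexa (0.31), Ctsa (0.31) and Ctsl (0.30, standard error 0.10) contributed, none of them alone when adjusted over the list alone. No gene passed over the transcriptome (0 of 14775 in limma, 382 at an unadjusted p under 0.05; smallest adjusted p 0.308). The nicotinamide enzyme Nampt came closest (0.67, standard error 0.15; 0.094 in AECII and -0.57 in PASMC), followed by Slc6a8 (0.46), the retromer subunit Vps26a (0.58), Wdr20 (0.87) and Uap1l1 (0.93; 0.0014 in AECII and -0.93 in PASMC).

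Another 6 lists responded differently to this extract before the correlation between genes was estimated. Among them were NRF2 genes (mean 0.25, adjusted p = 3.06e-06, and 0.155 with an estimated correlation), ATF4 targets (0.16, 0.00107, and 0.155 with an estimated correlation) and aldehyde metabolism (0.20, 0.0285, and 0.155 with an estimated correlation). The remaining 3 were iron handling (0.21, 0.0285, and 0.13 with an estimated correlation), hypoxia (0.18, 3e-04, and 0.167 with an estimated correlation) and cell cycle (-0.16, 3.07e-05, and 0.692 with an estimated correlation). For the nicotine-free extract no gene passed (0 of 14775 in limma, 393 at an unadjusted p under 0.05). Among the smallest p values were Rpap2 (0.42), L1td1, which lies near background in PASMC, and Krt15, near background. There 6 lists were called, and none with an estimated correlation. Among them were NRF2 genes (0.20, adjusted p = 0.000283, and 0.617 with an estimated correlation), lysosome (0.080, 0.00825, and 0.617 with an estimated correlation) and hypoxia (0.14, 0.017, and 0.664 with an estimated correlation). The others were cell cycle (-0.11, 0.0374, and 0.944 with an estimated correlation), ATF4 targets (0.12, 0.0413, and 0.664 with an estimated correlation) and chaperones (-0.076, 0.0413, and 0.617 with an estimated correlation).

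Because both extracts were compared with the same 8 controls, their changes share the controls' noise. Across genes they correlated at 0.49 in AECII and 0.56 in PASMC, against 0.50 in simulated data without an effect, so this correlation is no measure of a common response. With the controls split between the extracts the median correlation was -0.07 and -0.11. The split cannot show that a common response is absent. If conditions share a source, both sets of controls deviate from it in opposite directions, which makes this correlation negative. The simulated arrays were independent and did not hold such a source. The lower lysosome list under both extracts in PASMC likewise rests on 1 set of controls.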

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

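The tests with marker genes as covariates and the exact permutations of list means were chosen only after the results they bear on were seen. The splits of the arrays and the random lists were chosen before. The lysosome and NRF2 lists to which they were applied had the smallest p of their comparisons.

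Among 141 groups of values of named genes and list means, 17 held 1 array far from the other 7, and 7 would be expected because chance sets apart about 1 in 20 groups. In PASMC control array 2 this held for Fap (6.12, median of the others 9.98), Thy1 (11.81, others 13.32) and Cyp1b1 (10.07, others 11.13). Its partners in a trio described below had similar values. They were 6.49, 11.82 and 10.17 in nicotine-free array 5, and 4.57, 11.84 and 10.50 in nicotine-containing array 5. Fap and Thy1 were checked for far arrays in controls only. Far arrays of different conditions are therefore not independent of each other if trios share a source. PASMC control array 3 and nicotine-free array 4 each held both a low Chrna1 (3.59 and 3.68, others 6.82 and 6.75) and a low Hmox1 (12.77 and 12.33, others 14.10 and 13.81). Nicotine-containing array 6, of the same trio, had 4.755 for Chrna1 and 12.65 for Hmox1 without being set apart by this rule. Ctsk was low in array 2 of the nicotine-containing extract (10.59, others 11.05). In AECII, Hmox1 was low in nicotine-free array 2 (8.29, others 12.42), and Nqo1 was low in nicotine-free array 1 (8.25, others 9.18), nicotine-containing array 7 (7.88, others 9.13) and control array 6 (7.49, others 8.99). Control array 6 also had a low NRF2 mean (10.88, others 11.31) and a high Krt7 (14.23, others 13.87). AECII control array 1 was low in Chrnb4 (2.14, others 4.03) and Slc1a6 (2.03, others 3.19), and control array 3 in Sftpd (11.76, others 12.36). All these arrays were kept.

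The responses of AECII and PASMC differed for several lists, AECII minus PASMC. With the nicotine-free extract the differences were 0.205 for NRF2 genes, 0.121 for ATF4 targets, -0.076 for chaperones, -0.106 for the cell cycle, 0.141 for hypoxia and 0.080 for the lysosome. With the nicotine-containing extract they were 0.251 for NRF2 genes, 0.202 for aldehyde metabolism, 0.162 for ATF4 targets, -0.162 for the cell cycle, 0.184 for hypoxia, 0.167 for the lysosome and 0.209 for iron handling. With an estimated correlation the lysosome difference under the nicotine-containing extract was called (adjusted p = 0.0044) and the other 12 were not.

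Features without a gene name were tested in the same way. With the nicotine-containing extract 1 of 11276 was lower in PASMC (adjusted p = 0.0477, 454 at an unadjusted p under 0.05). The other comparisons within a cell type called 0 in limma, with 480, 427 and 454 of 11423 features at an unadjusted p under 0.05 in AECII (nicotine-free, nicotine-containing, and one against the other), and 380 and 437 in PASMC (nicotine-free, and one against the other).

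Random splits of the arrays show which counts chance can give. It can be excluded for the 8744 genes that differ between the cell types (1 of 100 splits, the real one, highest other 7490). For the 4 genes of PASMC with the nicotine-containing extract 2 of 100 splits, the real one included, gave as many (highest other 11). This does not exclude chance, as it is the most favourable of several treatment comparisons. A count of 0 excludes nothing, since all 100 splits give as many; the highest others were 1, 2 and 8 genes in AECII (nicotine-free, nicotine-containing, one against the other), 1 in PASMC with the nicotine-free extract, 62 between both extracts in PASMC, and 1 and 1 for the differences between cell types. For the numbers of lists called chance cannot be excluded: 78 of 100 splits gave as many for the nicotine-free extract in AECII (1 list, highest other 14), 63 for the nicotine-containing extract (3, highest other 14), 74 and 75 in PASMC (4 and 3 lists, highest others 14 and 12), and 100 for both extracts against each other (0 lists, highest others 13 in AECII and 16 in PASMC). Splits that call 62 genes or 16 lists where the real groups call none point to a structure of the arrays that the conditions do not explain. If arrays of different conditions share a source, splits that mix them unevenly can call more than the real groups. The counts of splits are then insensitive to an effect.

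The lower lysosome list of PASMC under the nicotine-containing extract was weighed against technical explanations. For this list 1 of 100 splits, the real one, gave so small a p (10.3 as minus log10 p, highest other 3.65). This argues against chance without excluding it. The list had the smallest p of 34, and the splits were judged on it alone. A shift shared by genes of the same brightness is argued against by 0 of 10000 random lists reaching the mean (-0.146, middle 95% -0.045 to 0.054). With the macrophage markers and Sftpc as covariates the change was -0.142 (95% interval -0.175 to -0.11), and Marco (9.82 and 9.88), Chil3 (9.39 and 9.13), Lyz2 (8.79 and 8.76) and Sftpc (5.77 and 6.20) had close means in controls and treated arrays, which argues against a different share of macrophages or alveolar type II cells. Open remain the normalisation before deposit, a processing batch that the labels do not give, and the unknown treatment of the controls. A different share of other epithelial cells, which these covariates did not cover, stays open too. A response of these cells to the extract may explain the pattern, as a hypothesis, since it was found and tested on the same arrays.

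The higher NRF2 list of AECII under the nicotine-containing extract was less secure in tests that treat arrays as independent. Its p was reached by 4 of 100 splits, the real one included (14.8 as minus log10 p, highest other 18.3). This does not exclude chance for the list with the smallest p of 34. The exact permutation of the list mean gave 0.0691 after adjustment. The splits and the permutation exchange arrays freely, so they are insensitive if conditions share a source. The AECII arrays of low Nqo1 form 1 trio described below (6-1-7), so a weak effect and a shared source cannot be told apart here. A shift shared by genes of the same brightness is argued against by 0 of 10000 random lists reaching the mean (0.233, middle 95% -0.015 to 0.037), and with epithelial markers as covariates the change was 0.239 (95% interval 0.1 to 0.378, against 0.029 to 0.437 without), while Krt8 (14.75 and 14.74) and Cdh1 (12.01 and 11.92) had close means in controls and treated arrays. A split with a smaller p than the real one shows that this list also varies together between arrays of 1 condition. An antioxidant response to the extract may explain the pattern, as a hypothesis, and normalisation or an unrecorded batch stay open. A different mix of epithelial cell types, which general epithelial markers do not tell apart, stays open too. In controls and treated arrays airway markers averaged 6.84 and 6.83, and alveolar type II markers 8.83 and 8.84.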

How the results depend on the processing

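Chosen only after results were seen were the residual components and the Sftpc limit; the other alternatives were planned. No alternative reversed the direction of a gene or list called in the main fit. Of 4813 values of genes 4737 kept their call or lack of one, 71 were weaker and 5 stronger. Of 293 values of lists 252 kept it and 41 were weaker. The gene values include genes that were not called, for which a change of sign counted as the same. An example is Hmox1 in AECII under the nicotine-free extract (-0.23, and 0.27 without nicotine-free array 2). The limits lie in the calls: changes of single genes in PASMC sit near the threshold, most lists owe their call to the preset correlation, and only the lysosome list of PASMC was called in every alternative run for it (adjusted p 3.59e-11 to 0.00048 with the nicotine-containing extract, and 4.27e-08 to 0.00273 with the nicotine-free extract). Where a count changed, the cause was not tested unless stated.

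The replicate numbers were also used as a block, although each array correlated best with an array of its own number in 5 of 24 cases in each cell type, and 5 of 24 same-number pairs in AECII and 9 of 24 in PASMC exceeded 0.1. With this block the genes called in PASMC with the nicotine-containing extract went from 4 to 0, and no other count changed.

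For the 4 genes of PASMC under the nicotine-containing extract, the count was 1 without a filter, 8 with the 50th percentile, 0 with only the 16 arrays compared, 0 with treat, 13 with array weights, 1 with the mean of all probes, 0 with runs of 8 accessions as a block and 0 with PASMC arrays with Sftpc at or below 6. Their adjusted p over all alternatives ran from 0.000175 to 0.572 for Uap1l1, 0.00425 to 1 for Kazn, 0.00207 to 1 for Ctsk and 0.00214 to 1 for Slc6a8. Array weights also gave 1 gene in PASMC with the nicotine-free extract, 1 gene (Nampt) for the difference between cell types under the nicotine-containing extract, and 2 and 5 lists in AECII (nicotine-free and nicotine-containing).

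With an estimated correlation the lists called were 0 and 0 in AECII and 1 and 1 in PASMC (nicotine-free and nicotine-containing), and fry gave 0, 0, 1 and 1. With PASMC arrays with Sftpc at or below 6 the nicotine-free extract called 2 lists, and with runs of 8 accessions as a block the nicotine-containing extract called 6 lists in AECII.

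Residual components as covariates gave 21 genes (1 component) and 39 genes and 7 lists (3 components) in PASMC with the nicotine-containing extract, 3 genes with the nicotine-free extract, 1 gene for the difference between cell types under the nicotine-containing extract and 6 lists in AECII under it. These counts are not findings: on simulated PASMC data without an effect 3 components made false calls in 18 of 20 simulations (median 221, highest 4624) and 1 component in 9 of 20 (highest 3853), against 1 of 20 without components (highest 3), and 64 of 100 splits of the real arrays gave as many as 39 genes (highest other 3290). Simulated PASMC data that did not hold the components of the real arrays gave fewer. There 3 components made 8 false calls against 9 without components, and 0 with shared sources and no effect. With 3 residual components and an estimated correlation the lists called were 0 and 0 in AECII and 2 in PASMC with the nicotine-free extract.

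Leaving out 1 array at a time gave 1 to 4 genes in PASMC with the nicotine-containing extract: 4 without control 2 or nicotine-containing array 1 (Ctsk not among them in the latter), and 1, Uap1l1, without any of the other 14. The nicotine-free extract in PASMC gave 0 to 1 genes (1 without control 2). Lists ranged from 1 to 3 for the nicotine-free extract in AECII (3 without nicotine-free 1 or 2 or control 3 or 8, 2 without control 6). For the nicotine-containing extract in AECII they ranged from 3 to 5 (5 without control 3, 4 or 5 or nicotine-containing 7, and 4 without control 2 or 8 or nicotine-containing 6 or 8). Between both extracts in AECII they ranged from 0 to 3 (3 without nicotine-containing 7, 1 without nicotine-free 2). In PASMC with the nicotine-free extract they ranged from 2 to 6 (2 without control 8, 3 without nicotine-free 1 or control 1, 3, 6 or 7, 5 without nicotine-free 3, 6 without nicotine-free 4 or 5). With the nicotine-containing extract they ranged from 3 to 5 (5 without control 2, and 4 without control 6 or nicotine-containing 3 or 6), and between both extracts from 0 to 2 (2 without nicotine-free 4). Calls or means of single lists also changed when 1 array was left out. If the trios of arrays described below share a source, leaving out 1 array unbalances the conditions. Such changes then need not come from an outlying array. In AECII, the NRF2 mean under the nicotine-free extract was 0.090 without control 6, and ATF4 targets under the nicotine-containing extract lost their call without it (0.080). In PASMC with the nicotine-free extract, cell-cycle genes lost theirs without nicotine-free 4 (0.081) or control 8 (0.090), hypoxia genes without control 3 (-0.081; -0.082 and still called without nicotine-free 5), and chaperones without nicotine-free 1, 4 or 5 or control 1, 4, 6, 7 or 8 (0.059 to 0.084). With the nicotine-containing extract, cell-cycle genes lost theirs without treated array 6 (0.065) and were at 0.099 without control 8.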

Other observations

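Chosen only after the result was seen were the genes of the opening paragraphs and, for the likeness of arrays, the tests of accession runs, of carried-over cells and of number combinations found in both cell types; the random rotations were chosen before.

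Both cultures held transcripts of macrophages. Marco, a scavenger receptor of alveolar macrophages, was higher in PASMC controls than in AECII controls (9.82 ± 1.95 and 7.32 ± 1.05; adjusted p = 0.0041), whereas of the 20 macrophage markers listed 5 were higher in AECII and 1 was lower. The chitinase-like Chil3 did not pass (9.39 ± 1.86 and 8.87 ± 0.95, adjusted p = 0.561). Lysozyme Lyz2 stood at 8.79 ± 1.85 and 10.00 ± 0.48, while the leukocyte marker Ptprc (3.19 and 3.43) and the endothelial Pecam1 (3.52 and 3.67) were near the floor in both. Krt8, a keratin of simple epithelia, was 14.75 ± 0.080 in AECII and 6.34 ± 2.92 in PASMC, and Cdh1 12.01 ± 0.24 and 4.09 ± 1.99. The standard deviations in PASMC mean that these transcripts differed strongly between arrays of 1 condition.

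Some genes named in other comparisons did not pass adjustment in PASMC under the nicotine-containing extract. Fnip2 stood at -0.57 (standard error 0.14, adjusted p = 0.337), Gnptg at -0.37 (0.096, 0.381), Vps26a at -0.41 (0.11, 0.362) and the nicotinamide phosphoribosyltransferase Nampt at -0.57 (0.11, 0.0892). The same genes in AECII were at -0.099, -0.011, 0.16 and 0.094, each with an adjusted p of 1.

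After the condition means were removed, trios of arrays, 1 from each condition, resembled each other mutually best. The trios (control, nicotine-free, nicotine-containing) in PASMC were 2-5-5, 3-4-6, 5-2-8, 6-1-7 and 8-3-3, and in AECII 3-4-5, 5-2-8, 6-1-7 and 7-6-1. In the first PASMC trio Chrna1 was 8.73, 8.66 and 8.81 and Sftpc 1.72, 2.07 and 2.00, and in the last Sftpc was 11.28, 10.26 and 11.21.

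Chance likeness along a few components is argued against, as 0 of 1000 random rotations reached the 5 trios of PASMC and 2 of 1000 the 4 trios of AECII. For PASMC, runs of 8 accessions are argued against by a mean correlation that was not higher within runs than between them (-0.009), while in AECII it was higher by 0.034. The combinations 5-2-8 and 6-1-7 occur in both cell types, which 4 of 10000 random draws of the numbers matched, so arrays of a trio may share a source that both cell types have, such as a mouse or a day of isolation. With markers regressed out 0 PASMC trios were left, so alveolar and macrophage cells carried over could be part of what such a source differs in, although 4 of 100 sets of random covariates left as few, and carry-over alone does not predict the same numbers in AECII. The labels do not link arrays to mice, so the trios are a hypothesis and were not used to pair arrays. The AECII arrays set apart by a low Nqo1 (control 6, nicotine-free 1, nicotine-containing 7) form trio 6-1-7. If trios share a source, leaving out 1 array of a trio unbalances the conditions, and tests that exchange arrays freely are insensitive.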
